A study of Mus musculus with 15 samples.

How the data were processed

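Total RNA of mouse liver was labelled with biotin and hybridised to 2 Illumina BeadChips, in 8 arrays of the glucose-infused wild-type controls and 7 arrays of the liver Prkar1a knockouts. BeadChip 1 held control replicates 1 to 4 and knockout replicates 1 to 3, and BeadChip 2 the remaining arrays of both groups. Groups and replicate numbers were taken from the labels. The deposited table of intensities gives for each probe and array the mean bead intensity on a linear scale, not yet normalized, per the file headers. The same deposited table gives a detection p-value and the number of beads per probe, per the file headers. Besides these there were 5 columns of a further array, with a name that matched no sample, which were not used. A further deposited table holds the authors' processed log2 values of 24825 probes. Each of its arrays had the same quartiles, so the values had been quantile normalized, with no centring per gene, and the exact steps are not given in the sources used here. GenomeStudio and R 2.15.0 are named in the submitters' processing notes. In the authors' table each array correlated with its own intensities at 0.998 or more, except control replicate 4 at 0.893. Mean bead numbers per probe were 28.0 to 33.5 on BeadChip 1 and 38.5 to 39.4 on BeadChip 2.

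Intensities were corrected for background, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, with an offset of 16. Tables were read with data.table (version 1.17.8). Probes with a detection p under 0.05 on at least 7 arrays were kept, which left 12194 of 25697. Gene symbols came from the deposited table. Of its probes 24624 had a symbol found in a RefSeq gene table of assembly GRCm38.p6, 3891 of them under an older symbol that was updated, and 1073 kept the file's symbol. Date-like symbols of 31 probes were restored from the gene definition. Each gene was represented by its probe with the highest mean over all arrays, giving 9273 genes, of which 2215 had several tested probes and 713 of those had probes with differences in both directions. No genome build is named in the tables, so no positions are given.

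Knockout and control were compared with limma (lmFit and eBayes, two-sided, no covariates) with Benjamini-Hochberg adjustment over all genes at 0.05. Fold values are on the scale of background-corrected intensities with the offset, which understates changes of dim genes. Gene lists for liver metabolism, signalling, stress, cell types and clock were written before the data were examined. Of these, 33 had at least 2 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry, which tests whether a list's genes move one way and does not compare them with other genes. With an estimated correlation 0 of the 33 lists passed, 6 had an unadjusted p under 0.05, and 15 passed with fry. The B cell list had 1 measured gene and was not tested. The list of secreted peptides includes Kiss1, the gene in the study's title, and the list of PKA subunits includes the targeted gene, so these 2 are not independent evidence. Some lists share genes, among them the periportal and the urea cycle lists, and shifts of such lists are not independent of each other.

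The rule for the genes named in the text was also set before the data were examined. It took Prkar1a and Kiss1, the 10 largest rises and 10 largest falls among changed genes with the same sign on both BeadChips, leaving out predicted genes, and up to 4 members of each list that passed or had at least 3 changed members. Other lists gave up to 2 changed members. Pck1, G6pc, Ifit3 and Arntl were singled out after their values were seen, as members that a reader would look for.

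The tests were tried on simulated data for the same 9273 genes, in 20 runs of 200 changed genes each. They found 20.3% of genes changed by 0.5 on the log2 scale, 76.9% of those changed by 1 and 98.4% of those changed by 2. Of the genes called over all runs, 6.91% were unchanged. The median was 1 unchanged gene called per run, so these false calls were spread unevenly over the runs. A shifted list was found in 20 of 20 runs, and 0 of 600 unshifted lists were called. Those lists were drawn from random genes, so they do not show how often lists of co-regulated genes are called by chance. Estimated correlations of the real lists reached 0.86 for neutrophil markers, and were 0.22 for interferon and 0.15 for urea cycle and amino acid genes. Other splits of the real arrays into groups of 8 and 7 called a median of 5 lists. Sex-linked transcripts were checked on every array. Xist was detected on 0 of 15 arrays, and Eif2s3y on 15 of 15. The most similar pair of arrays, knockout replicates 1 and 2, correlated at 0.990 and shared 0 identical values, so neither was a copy of the other. All arrays were counted as separate samples, although this check cannot show that they came from separate animals.

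Alternatives covered the background correction and its offset, the normalization, the authors' processed values, the filter on dim probes, the treatment of several probes per gene, the BeadChip as a block and each BeadChip alone, the replicate number as a block, array weights, an intensity trend in the variance, stricter thresholds and each array left out in turn. Fits without control replicates 1, 3 and 4, the arrays farthest out on the leading principal components, and with the leading within-group component as a covariate were added after the data were seen.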

Results

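Liver RNA in 15 samples from mice of the C57Bl/6J background was measured on 2 Illumina expression BeadChips. The 7 knockout samples came from animals with a floxed Prkar1a gene, in which an adenovirus carrying Cre recombinase was used to delete the gene in the liver. The 8 control samples came from wild-type animals given glucose by vein for 3 days to bring their glucose to the level of the knockouts. Prkar1a encodes a regulatory subunit of protein kinase A (PKA) that holds the kinase inactive until cAMP binds, so the comparison asked which liver transcripts differ when this brake is missing and glucose is matched. Of the 25697 probes on each array, 11087 to 13121 were detected on 14 arrays. Control replicate 4 was dimmer, with 8889 probes detected and a 95th percentile of intensity of 200, against 1346 to 2998 on the other 14 arrays. The number of arrays limits the precision of all values. The labels number the replicates without saying that each was a separate animal, so the p-values measure the spread between these samples, which may in part be technical. Genotype and infusion differed together between the groups, and whether the controls received a virus is not given in the sources used here.

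Prkar1a, the targeted gene, was 5.24-fold lower in knockout liver, at a log2 normalized intensity of 8.77 ± 0.32 (SD, n = 7) against 11.16 ± 0.11 (SD, n = 8) in control liver. The groups did not overlap, and Prkar1a fell by 2.39 on the log2 scale with a standard error of 0.13 (limma, Benjamini-Hochberg adjusted p = 6.78e-09). It was still detected on all 7 knockout arrays. Whether its probe lies in the deleted part of the gene is not given in the sources used here. Kiss1, which encodes the precursor of the kisspeptin peptides and is the gene named in the study's title, had the largest rise in the background-corrected, quantile-normalized values. It was 14.4-fold higher in knockout liver, at 8.86 ± 0.42 (SD, n = 7) against 5.01 ± 0.30 (SD, n = 8), with a log2 difference of 3.85 and a standard error of 0.18 (limma adjusted p = 1.63e-09). Kiss1 was detected on 4 of the 8 control arrays and on all 7 knockout arrays, so its control level lay close to background and its fold depends on the background correction. Both in the authors' processed values and in quantile-normalized intensities without background correction, the Kiss1 log2 difference was 2.18. That of Egln3 was larger there at 3.22, as it was with a background offset of 50 (3.45 against 2.91) and with array medians set equal (3.65 against 3.57). With the BeadChip as a block the log2 difference was -2.40 for Prkar1a and 3.84 for Kiss1. On BeadChip 1 alone these were -2.64 and 3.95, and on BeadChip 2 alone -2.19 and 3.73.

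**Figure D1:**
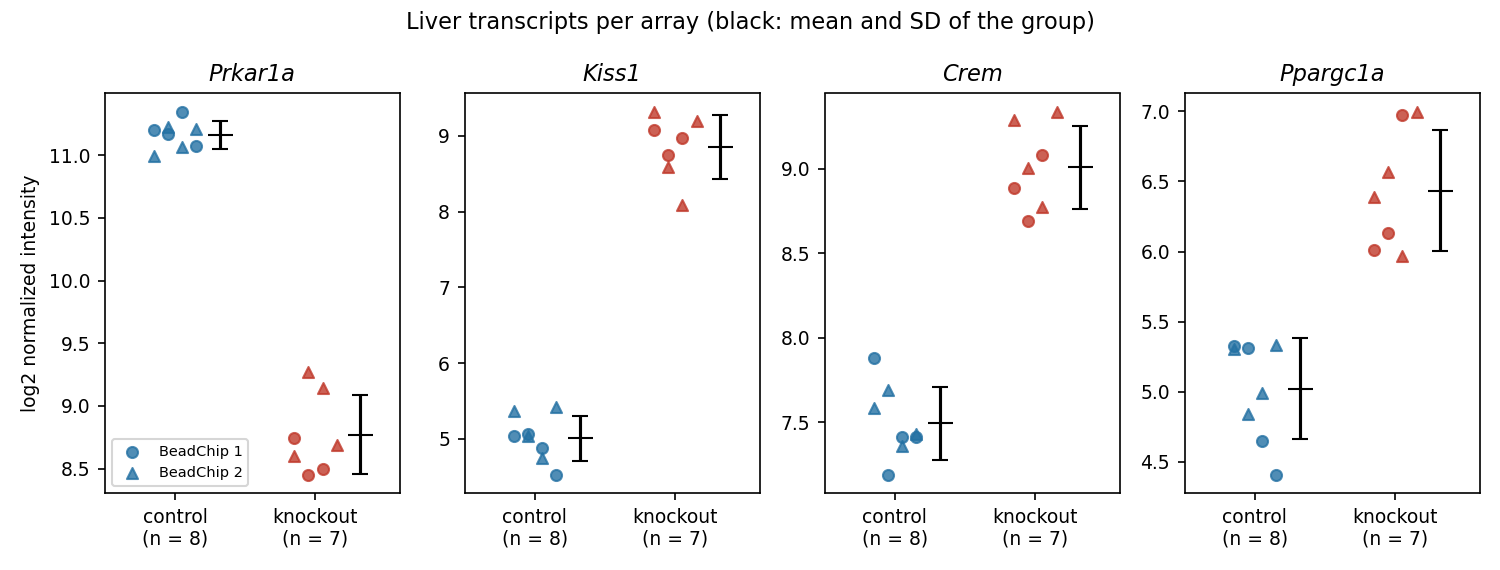
Log2 normalized intensity (vertical axis) of Prkar1a, Kiss1, Crem and Ppargc1a on each of the 8 control (blue) and 7 knockout (red) arrays, with circles for BeadChip 1, triangles for BeadChip 2 and the group mean ± SD in black. Prkar1a lay lower on every knockout array than on any control array, and the other 3 genes lay higher on every knockout array; the vertical axes do not start at 0.

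Across the 9273 genes tested, 976 differed between knockout and control liver, 500 of them higher and 476 lower in the knockouts (limma with Benjamini-Hochberg adjustment at 0.05). Of these, 159 were at least 2-fold higher and 93 at least 2-fold lower. All 976 had the same sign of difference on both BeadChips, which is largely built in, since they were selected over both together. Over all 9273 genes the log2 differences on the 2 BeadChips correlated at 0.578. With the BeadChip as a block 1262 genes passed, and with fewer arrays 198 passed on BeadChip 1 alone and 186 on BeadChip 2 alone. The count was 581 when array medians were set equal in place of quantile normalization and 2112 with array weights. Without control replicate 4, the dim array, 1303 genes passed. Of the 224 changed genes with several tested probes, 15 had probes pointing in both directions. Of 33 gene lists fixed before the data were examined, 4 shifted higher and 5 lower (camera with a preset correlation and Benjamini-Hochberg adjustment), against 0 and 0 with a correlation estimated per list, where 6 had an unadjusted p under 0.05. As many shifted lists came from 15 of 100 splits of the arrays into groups of 8 and 7, the real one included.

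The next largest rises in these values were in Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, which was 11.8-fold higher (log2 difference 3.56, limma adjusted p = 1.81e-09), and in the protocadherin Pcdh20, 8.28-fold higher (3.05, adjusted p = 2.19e-06). Ntrk2, the receptor for brain-derived neurotrophic factor, was 6.99-fold higher. Cdc42ep5, Bmper (a binding protein of bone morphogenetic proteins), Mmd2, Hip1r and the interferon-induced GTPase Tgtp1 were higher by log2 differences of 2.58 to 2.62. Zap70, a tyrosine kinase of T cell receptor signalling, was 5.71-fold higher (log2 difference 2.51, adjusted p = 2.89e-06), and its other tested probe pointed the same way. In the background-corrected values the largest fall was in the antimicrobial peptide gene Defb1, 10.9-fold lower in knockout liver, where it was detected on 3 of 7 arrays against 8 of 8 control arrays (log2 difference -3.45, adjusted p = 7.63e-06). Serpina4-ps1 followed at 7.50-fold lower. Dio1, the liver deiodinase that converts thyroxine to its active form, was 4.15-fold lower (log2 difference -2.05, adjusted p = 7.05e-05). Arrdc3 fell by 2.08, Cpsf4l by 2.04 and the water channel Aqp4 by 1.99 on the log2 scale. The falls of Obp2a (log2 difference -2.26), the lipid droplet gene Cidec (-1.94) and the carbonyl reductase gene Cbr3 (-1.92) also passed, although the groups overlapped for these 3 genes. Sizes of dim genes depended on the background correction. Without it the log2 difference was 1.44 for Ntrk2, 1.74 for Pcdh20, 1.67 for Bmper, 1.68 for Hip1r and 1.69 for Tgtp1. It was then -1.92 for both Defb1 and Serpina4-ps1, smaller in size than the -2.12 of Prkar1a, and -1.04 for Cpsf4l, -0.88 for Aqp4, -1.13 for Obp2a and -1.11 for Cidec.

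**Figure D2:**
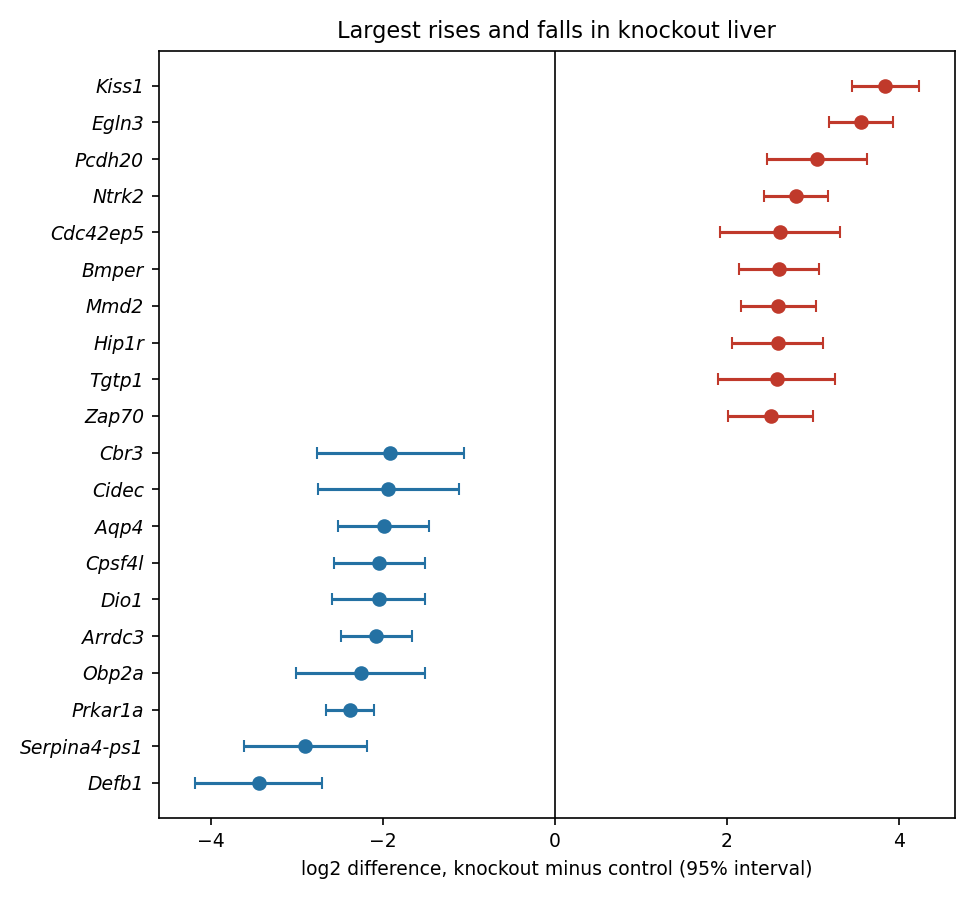
Log2 difference, knockout minus control (horizontal axis), with its 95% interval from the limma fit, of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) among the changed genes, over 7 knockout and 8 control arrays. The rises range from 2.51 for Zap70 to 3.85 for Kiss1 and the falls from -1.92 for Cbr3 to -3.45 for Defb1, and no interval crosses 0.

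Among the regulators that answer to cAMP and its transcription factor CREB, 4 of 16 measured genes rose, none fell and 12 did not pass, with 4 also passing when adjusted over the list alone. Crem, a CREB-family factor that is itself induced by cAMP, was 2.86-fold higher (9.01 ± 0.25, n = 7, against 7.49 ± 0.22, n = 8; limma adjusted p = 1.71e-06). Ppargc1a, the coactivator PGC-1α of hepatic gluconeogenesis, was 2.66-fold higher (limma adjusted p = 0.000226). The phosphodiesterase gene Pde10a was 2.40-fold higher and Irs2, an adaptor of the insulin receptor, 3.98-fold higher. Pde10a was detected on 3 of 8 control arrays and did not pass with array medians set equal (limma adjusted p = 0.0814). Without background correction the log2 difference was 0.47 for Pde10a, 0.56 for Ppargc1a and 1.01 for Irs2. The list as a whole did not pass (camera adjusted p = 0.0536, median log2 difference 0.09), although its adjusted p lay between 0.0293 and 0.0495 without control replicate 2, 4, 5 or 6 or knockout replicate 1, 2 or 5. It was 0.00468 with every probe tested separately, 0.0254 on BeadChip 2 alone and 0.617 over the genes detected on all 15 arrays. Of the 6 measured PKA subunits and inhibitors, Prkar1a was the only one to change, in a list that holds the targeted gene (camera adjusted p = 0.0747, and 0.0491 or 0.0468 without knockout replicate 1 or 2).

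Genes of the urea cycle and of amino acid catabolism and uptake were higher in knockout liver, with 14 of 32 measured members risen, none fallen and 18 not passing. When adjusted over the list alone, 19 rose. Agxt, which converts glyoxylate to glycine, was 3.44-fold higher, and the transsulfuration gene Cbs 2.82-fold higher. The glutaminase gene Gls2 was 2.58-fold higher and Nags, whose product makes the activator of the urea cycle's entry enzyme, 1.72-fold higher (limma adjusted p = 6.3e-06 to 0.00063 for these 4 genes). The list shifted higher with a median log2 difference of 0.61 (camera adjusted p = 4.5e-09), which did not pass with a correlation estimated for the list (adjusted p = 0.217 with an estimated correlation). Its median was 0.59 with the BeadChip as a block, 0.72 on BeadChip 1 and 0.45 on BeadChip 2, and each of these passed. Of 13 measured periportal genes, 3 rose and 10 did not pass. Sdsl was 3.65-fold higher, Sds, the serine dehydratase that feeds pyruvate, 3.01-fold higher, and Gls2 is also on this list. Sds and Gls2, among the 3 risen genes, belong to the urea cycle and amino acid list as well. Both lists were written to hold Arg1, Cps1, Ass1, Hal and Uroc1 too, so their shifts are not independent. The periportal list had a median log2 difference of 0.33 (camera adjusted p = 0.00359; adjusted p = 0.254 with an estimated correlation), with 0.33 with the BeadChip as a block, 0.30 on BeadChip 1 and 0.35 on BeadChip 2. There were 5 risen and 1 fallen periportal genes when adjusted over the list alone.

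In gluconeogenesis, Sds, the mitochondrial carrier gene Slc25a25 (1.86-fold) and the alanine aminotransferase gene Gpt (1.61-fold) rose, Slc37a4, the glucose-6-phosphate transporter gene, fell (2.30-fold) and the other 9 of the 13 measured genes did not pass. The fall of Slc37a4 (limma adjusted p = 0.0455) was lost when any of 11 single arrays was left out, with an adjusted p of up to 0.0982 without knockout replicate 8. Adjusted over the list alone, 4 rose and 1 fell. Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase, differed by 0.93 on the log2 scale without passing (limma adjusted p = 0.165), but passed with the BeadChip as a block (log2 difference 1.03, adjusted p = 0.0108). G6pc, the catalytic subunit of glucose-6-phosphatase, differed by 0.04 (adjusted p = 0.944). The list's median log2 difference was 0.49 (camera adjusted p = 0.0536, and 0.0488 with the BeadChip as a block). The median was 0.15 with no filter on dim probes, 0.32 with every probe tested separately and 0.21 without control replicates 1, 3 and 4. Without control replicate 2, 4, 5 or 8 or knockout replicate 1, 4 or 7 its adjusted p lay between 0.0274 and 0.0499.

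Genes that respond to glucose and to the factor ChREBP were lower in knockout liver, with 2 of 12 measured members fallen and 10 not passing, and 3 fallen when adjusted over the list alone. Thrsp, a regulator of lipid synthesis, was 3.24-fold lower (limma adjusted p = 0.000675) and Slc2a2, the hepatic glucose transporter GLUT2, 2.33-fold lower (limma adjusted p = 0.000102). The list's median log2 difference was -0.41 (camera adjusted p = 0.0165; adjusted p = 0.217 with an estimated correlation). It was -0.42 with the BeadChip as a block, -0.45 on BeadChip 1, and -0.29 without passing on BeadChip 2 (camera adjusted p = 0.0722). Slc2a2 was the only gene to change among 12 of glucose uptake and glycolysis (camera adjusted p = 0.216). In glycogen metabolism Pygl, the liver glycogen phosphorylase, was 1.54-fold lower, and 2 subunits of its activating kinase moved apart, with Phkb 1.67-fold lower and Phkg2 1.96-fold higher. The other 7 of the 10 measured glycogen genes did not pass (camera adjusted p = 0.144). Counts adjusted over the list alone were the same for glycolysis and glycogen, at 1 fallen, and at 1 risen and 2 fallen. Pygl did not pass with array medians set equal (limma adjusted p = 0.144), nor Slc2a2 with the mean over its probes (0.171).

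Fatty acid oxidation and ketogenesis genes were lower in knockout liver, with 5 of 22 measured members fallen, 1 risen and 16 not passing. Adjusted over the list alone, 12 fell and 2 rose. Angptl4, a secreted inhibitor of lipoprotein lipase, was 1.83-fold lower (limma adjusted p = 0.0219), whereas the acyl-CoA thioesterase gene Acot1 was 2.30-fold higher (limma adjusted p = 0.000495). The list's median log2 difference was -0.41 (camera adjusted p = 0.00359; adjusted p = 0.217 with an estimated correlation), with -0.41 with the BeadChip as a block, -0.52 on BeadChip 1 and -0.24 on BeadChip 2. It was -0.14 with every probe tested separately. With array medians set equal in place of quantile normalization its camera adjusted p was 0.0502, and Angptl4 did not pass (limma adjusted p = 0.0936). In fatty acid and triglyceride synthesis 4 of 18 measured genes fell, 1 rose and 13 did not pass. Thrsp, Cidec and the adipogenic receptor gene Pparg (1.65-fold) were lower, and the desaturase gene Fads2 was 2.95-fold higher. That list did not pass as a whole (camera adjusted p = 0.0907), but did without control replicate 4 (0.0327) or knockout replicate 5 (0.0205). Adjusted over the list alone, 4 fell and 1 rose. Pparg did not pass with array medians set equal (limma adjusted p = 0.0783). None of the 18 measured genes of cholesterol synthesis passed limma's adjusted p, and 3 were higher at an unadjusted p under 0.05 (0 when adjusted over the list alone; camera adjusted p = 0.108, and 0.0483 without control replicate 5).

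Drug-metabolising enzymes were lower in knockout liver, with 5 of 27 measured members fallen, none risen and 22 not passing, and 8 fallen when adjusted over the list alone. Cyp2c37 was 1.81-fold lower and Cyp2e1, a pericentral enzyme that oxidises ethanol, 1.42-fold lower. The median log2 difference was -0.34 (camera adjusted p = 0.00904; adjusted p = 0.217 with an estimated correlation), with -0.37 with the BeadChip as a block, -0.54 on BeadChip 1 and -0.26 on BeadChip 2, and -0.58 with array weights. The camera adjusted p was 0.0501 with array medians set equal and 0.115 over the genes detected on all 15 arrays. Cyp2c37 and Cyp2e1 did not pass with array medians set equal (limma adjusted p = 0.154 and 0.0878). Pericentral genes went both ways, with 4 of 12 measured members risen, 3 fallen and 5 not passing (camera adjusted p = 0.937). Oat, the ornithine aminotransferase, was higher by a log2 difference of 0.58 and the glutamate transporter gene Slc1a2 1.65-fold higher, while Cyp2e1 was lower. In bile acid synthesis and transport 2 of 16 measured genes rose, 3 fell and 11 did not pass (camera adjusted p = 0.575). Abcg8 and Abcg5, the paired sterol exporters of the canalicular membrane, were 3.31-fold and 2.35-fold higher, and Abcb4, the phospholipid exporter, was 1.56-fold lower, but did not pass with array medians set equal (limma adjusted p = 0.144). In counts adjusted over the list alone, 4 pericentral genes rose and 5 fell, and 2 bile acid genes rose and 5 fell.

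Interferon-response genes were higher in knockout liver, with 15 of 26 measured members risen, none fallen and 11 not passing. Adjusted over the list alone, 16 rose and 1 fell. Gbp6, Tgtp1 and Igtp, which encode GTPases induced by interferon gamma, were 2.51-fold, 5.98-fold and 3.31-fold higher, and the chemokine gene Cxcl9 3.55-fold higher (limma adjusted p = 7e-05 to 0.000132). Ifit3, a gene induced by type I interferon, differed by -0.24 on the log2 scale without passing (limma adjusted p = 0.359). The list's median log2 difference was 0.73 (camera adjusted p = 7.43e-09; adjusted p = 0.217 with an estimated correlation), with 0.75 both with the BeadChip as a block and on BeadChip 1, and 0.70 on BeadChip 2. Markers of T and NK cells shifted higher with it, at a median log2 difference of 0.56 (camera adjusted p = 0.0229; adjusted p = 0.441 with an estimated correlation), though none of the 10 measured markers passed alone in limma and 3 were higher at an unadjusted p under 0.05. Cd3g differed by 0.75 (limma adjusted p = 0.093, and 0.0254 without control replicate 6) and Ccl5 by 0.68 (0.134, and 0.00626 without knockout replicate 5). The T and NK cell list did not pass with array medians set equal (median 0.34, camera adjusted p = 0.0502), without control replicate 8 (0.0613), over the genes detected on all 15 arrays (0.269) or on BeadChip 2 alone (median 0.32, camera adjusted p = 0.232), against medians of 0.56 with the BeadChip as a block and 0.72 on BeadChip 1. Of its markers 0 passed when adjusted over the list alone. The list's median was 0.25 without background correction and in the authors' processed values, and 0.32 with no filter on dim probes.

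Markers of sinusoidal endothelial cells shifted lower, with 2 of 12 measured members fallen and a median log2 difference of -0.37 (camera adjusted p = 0.0197; adjusted p = 0.441 with an estimated correlation). Oit3 was 2.13-fold lower (limma adjusted p = 0.0134). Stellate cell and matrix genes shifted lower as well, with 2 of 14 fallen and a median of -0.50 (camera adjusted p = 0.0229; adjusted p = 0.441 with an estimated correlation). Reln, made by stellate cells, was 1.71-fold lower and the smooth muscle actin gene Acta2 2.04-fold lower; with array medians set equal neither passed (limma adjusted p = 0.0949 and 0.0507). Among these genes 3 endothelial and 2 stellate ones fell when adjusted over the list alone. With the BeadChip as a block the medians were -0.35 and -0.46, and both lists passed. Neither list passed on BeadChip 1 alone, with medians of -0.11 and -0.02, against -0.60 and -0.66 on BeadChip 2. Without background correction the medians were -0.24 and -0.18, and that of the stellate list was -0.22 with no filter on dim probes and -0.26 with array weights, where it did not pass (camera adjusted p = 0.127). Without knockout replicate 4 the camera adjusted p was 0.0538 for the endothelial list and 0.0834 for the stellate list, whose median was then -0.28. Over the genes detected on all 15 arrays the endothelial list did not pass (camera adjusted p = 0.0810). The stellate list also missed the threshold without control replicate 7 (0.0535) or 8 (0.0674). Of 16 macrophage and Kupffer cell markers 2 fell, among them Cd14, 2.28-fold lower, and 14 did not pass (camera adjusted p = 0.228). The macrophage list had a median log2 difference of 0.40 on BeadChip 1 (camera adjusted p = 0.327) and passed on BeadChip 2 at -0.65 (0.00107). The Cd14 log2 difference was -0.49 without background correction. Of 4 cholangiocyte markers Spp1 fell, by 1.01 on the log2 scale (camera adjusted p = 0.144). None of 8 neutrophil markers or 4 red blood cell transcripts passed in limma, and 0 did so at an unadjusted p under 0.05 (camera adjusted p = 0.96 and 0.221). At the preset correlation of 0.01 the neutrophil list passed on each BeadChip alone in opposite directions. Its median log2 difference was 1.32 on BeadChip 1 (camera adjusted p = 0.00586) and -0.99 on BeadChip 2 (0.017). The estimated correlation of this list was 0.86, so both p-values are too small. A difference between BeadChips was not tested for the list, and gene by gene 0 of 9273 genes passed for it (limma adjusted p). Adjusted over the list alone, 2 macrophage markers and 1 cholangiocyte marker fell and 0 neutrophil or red blood cell genes passed.

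**Figure D3:**
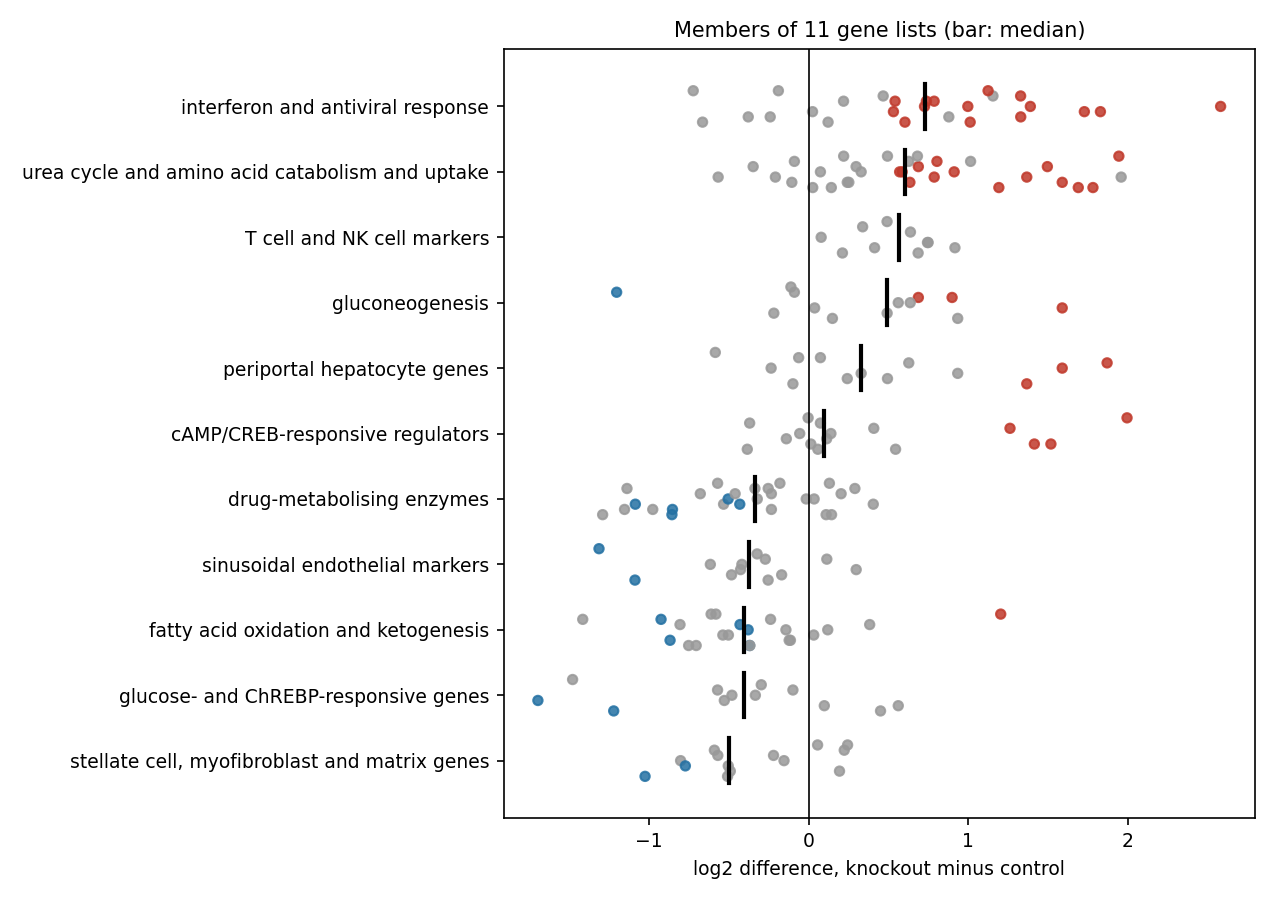
Log2 difference, knockout minus control (horizontal axis), of each measured member of the 11 gene lists with the smallest camera p, over 7 knockout and 8 control arrays, with a black bar at the list median. Members with an adjusted p under 0.05 over all genes are red (higher) or blue (lower) and the others grey; medians range from -0.50 for stellate cell and matrix genes to 0.73 for interferon genes.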

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

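Of the tests in this part, those of the BeadChip as a source of the changed genes, of array brightness and of gene lists along the leading within-group component were chosen after the result was seen.

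Among 198 groups of values checked (each named gene within the controls or within the knockouts), 16 had 1 array far from the rest of its group, where chance alone gives about 1 in 20. Control replicate 4, the dim array, held 6 of the 16. Its log2 intensity was low for Acot3 (6.24), Cx3cr1 (4.54), Bub1b (6.60), Clec4g (11.14), Ugp2 (9.80) and the cytotoxic lymphocyte gene Prf1 (4.78). Among the knockouts, replicate 4 was high for Obp2a (7.44) and low for Col4a1 (7.99), and replicate 5 was high for Thrsp (11.31) and low for Ccl5 (6.75). Knockout replicate 7 was low for Elovl3 (9.09) and Tbx3 (5.37), and knockout replicate 8 high for Acot3 (10.01) and low for Pygl (12.46). Nags was low in knockout replicate 3 (10.86) and Gpt high in control replicate 8 (11.50).

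For the 976 genes that differed between knockout and control liver, chance is argued against, since 1 of 100 splits of the arrays, the real one, gave as many. It is not excluded, because 100 splits cannot show a share below 1 in 100. The highest other split gave 894. That other split had 6 arrays of BeadChip 1 in its smaller group, and setting BeadChip 1 against BeadChip 2 called 761 genes, so the arrays carry a BeadChip structure; the difference between BeadChips is argued against as the source of the knockout result by the 1262 genes called with the BeadChip as a block. Of the 100 tested genes nearest Prkar1a 10% were called, against 10.5% of the genes elsewhere. These shares argue against a segment of another strain around the floxed gene as a main source of the calls. The 100 genes held 1.07% of called genes, a share kept low by their number among the 8874 ordered genes. Strain segments elsewhere are argued against by 88 neighbouring pairs of called genes, below the 95th percentile of 109 in 10000 shuffles (one-sided permutation p = 0.772). Loss of Prkar1a and the glucose infusion stay open together, because they differed between the same groups, and so does the adenovirus, which the labels name for the knockouts and leave unsaid for the controls.

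The number of shifted gene lists could not be separated from chance. Of 100 splits, the real one included, 15 gave at least its 9 lists. The highest other count, 13, came from splits with 3 or 4 knockout arrays in the smaller group. Some splits were less even, such as one with 6 knockout arrays in the smaller group and 11 lists. Uneven splits carry part of the real difference, so the shares are not pure chance rates. For single lists the counts below, out of 100, again include the real split. A camera p as small as the real one came from 2 splits for urea cycle and amino acid genes and from 4 for interferon genes. It came from 6 for drug-metabolising enzymes, 7 for periportal genes, 9 for glucose-responsive genes, 14 for fatty acid oxidation, 19 for T and NK cell markers and 25 each for endothelial and stellate cell markers.

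Interferon genes were higher in knockout liver at a median log2 difference of 0.73, alongside T and NK cell markers, and neither list passed with an estimated correlation (adjusted p = 0.217 and 0.441). More T and NK cells as the whole source are argued against, since the median was 0.60 with each array's mean of the 10 T and NK cell markers as a covariate (camera p in the limma fit = 5.24e-08 with the preset correlation). With that covariate 9 of the 26 interferon genes passed in limma, against 15 without it. A mean of so few markers is noisy and removes only part of such an effect. Within groups the interferon and T and NK cell means followed each other over the 15 arrays, at Pearson r = 0.554 (permutation p = 0.0399), Spearman rho = 0.711 (permutation p = 0.00351) and r = 0.652 without knockout replicate 5 and control replicate 6. The injected adenovirus cannot be told apart from the loss of Prkar1a, since 0 arrays are described as coming from animals with the virus and an intact gene, and whether the controls received a virus is not given in the sources used here. Both may contribute, and neither was tested apart from the other.

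The leading principal component held 29.6% of the variance. It set control replicates 3, 1 and 4 apart at scores of -57.9, -40.0 and -31.9, against -6.06 to 35.4 on the other 12 arrays. Its mean score was -13.5 ± 27.3 (SD) in the controls and 15.5 ± 13.5 (SD) in the knockouts. The component was thus not independent of the groups, and a technical source of it would enter the knockout comparison. Differences in RNA integrity or labelling stay open as its source. Across 2215 genes, 2 probes of a gene followed this component less alike (r = 0.268) than they followed the group (r = 0.709). The difference was -0.44, with a 95% interval of -0.481 to -0.399. It cannot decide the question, because probes were compared by their correlation with the component but by limma's t for the group. Genes are also not independent replicates. Control replicates 3 and 1 had 95th percentiles of intensity of 1863 and 2929, within the 1346 to 2998 of all arrays but control replicate 4. This argues against array brightness for control replicates 3 and 1. Brightness and the component correlated over all 15 arrays at Pearson r = 0.289 (permutation p = 0.295) and Spearman rho = -0.129 (permutation p = 0.650). The r of 0.155 without control replicate 4 and knockout replicate 8 leaves out the dim array, for which brightness stays open. Control replicates 3, 1 and 4 all lay on BeadChip 1 and had the fewest detected probes among the controls (11087, 11432 and 8889). Control replicates 3 and 1 also had the lowest mean bead numbers of all arrays. Control replicate 2 and knockout replicates 1 to 3 lay on BeadChip 1 too, at scores of -6.06 to 19.5. BeadChip, detection and bead number were not tested against the component, so they stay open as sources. Without control replicates 3, 1 and 4, 896 genes differed, 655 of them among the 976. A biological source of it stays open: the 33 gene lists were tested only along the leading component within groups, a different one on which control replicate 4 scored -0.148, and there none passed in camera (lowest adjusted p = 0.258; unadjusted p = 0.0124 for bile acid, 0.0188 for ribosomal, 0.0246 for lipid synthesis and 0.0313 for glycolysis genes).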

How the results depend on the processing

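The fits without control replicates 1, 3 and 4 and with the leading within-group component as a covariate were chosen after the data were seen, and all other alternatives before. Prkar1a stayed lower and Kiss1 higher at an adjusted p of at most 0.000599 and 0.000303 under all alternatives that tested them (log2 differences of -2.64 to -2.12 and 2.18 to 3.96); Kiss1 was not among the genes detected on all 15 arrays. Of 102 named genes, 87 passed, 30 of them under every alternative that tested them, single BeadChips included. Several of the 30, such as Ntrk2, Pcdh20 and Defb1, were like Kiss1 not tested over the genes detected on all 15 arrays. Leaving out 1 array at a time, 79 of the 87 kept their call. The other 8 lost it, at adjusted p values of up to 0.0984 (Cyp1a2), 0.0982 (Slc37a4), 0.0949 (Cx3cr1), 0.0884 (Lyve1), 0.0846 (Cyp2c50), 0.0843 (Ehhadh), 0.0714 (Slc10a1) and 0.0648 (Acaa1b). With array medians set equal 22 named genes lost their call. The authors' processed values shared 901 calls with the 976, all in the same direction. Low signal over background limits Kiss1, which was detected on 4 of 8 control arrays. Except where stated, the cause of the shifts given here was not tested.

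The count of changed genes was 581 with array medians set equal (242 lower), 198 on BeadChip 1 (108 higher, 90 lower) and 186 on BeadChip 2 (125 higher, 61 lower), where fewer arrays were tested. It was 2112 with array weights (1026 higher, 1086 lower) and 1674 with the within-group component as a covariate (863 higher, 811 lower). The rise with the within-group component is largely built in, since that covariate comes from the spread of these same genes around their group means. At an adjusted p under 0.01 in limma the count was 386 (218 higher, 168 lower), and at 2-fold or more 252 (159 higher, 93 lower). With the replicate number as a block the count was 656 (331 higher). Whether arrays of the same number form pairs was not tested and stays open. Correlations of their deviations were -0.272 to 0.406, with 4 of 7 over 0.1, and 3 of 14 arrays were closest to their own number. Without 1 array the count ranged from 701 to 1303, with 359 to 589 higher and 328 to 714 lower, and the highest value of each came without control replicate 4. The effect of the knockout differed between BeadChips in 0 genes at limma's adjusted p and in 505 at an unadjusted p under 0.05.

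Of the 9 shifted lists, 4 were higher and 5 lower. With array medians set equal 7 were higher and 2 lower, with no filter 8 were higher, over genes detected on all 15 arrays 3 were lower, on BeadChip 1 3 were lower and on BeadChip 2 7 were higher. With an estimated correlation 0 were higher and 0 lower, and with fry, which does not compare a list with other genes, 7 and 8. Without 1 array, 4 to 7 were higher (7 without control replicate 5) and 3 to 7 lower (3 without knockout replicate 4). The stellate list missed the threshold with array weights (adjusted p = 0.127), and with fry the endothelial and stellate lists stood at 0.0605 and the T and NK cell list at 0.0652; adjusted p over all alternatives ranged from 0.000617 to 0.450, from 0.000311 to 0.694 and from 0.000955 to 0.441 for these lists. For the other 6 shifted lists it reached at most 0.254, with an estimated correlation. Glucose-responsive genes also missed it with medians set equal (0.0932) or probes averaged (0.068), and over genes detected on all 15 arrays the endothelial (0.081) and T and NK cell lists (0.269) missed it. The gluconeogenesis list, at 0.0536, passed under 10 alternatives fixed beforehand, single arrays left out and fry not counted, with the lowest adjusted p, 0.0047, with medians set equal. With medians set equal the lists of cholesterol synthesis (0.0304), cell cycle (0.0391) and respiratory chain genes (0.00185) passed as well.

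Directions by camera changed only in 9 lists that did not pass and in Dcn (log2 difference 0.02 on BeadChip 1) and G6pc (-0.040 on BeadChip 1, -0.052 with the replicate block, -0.068 to 0.14 without 1 array). Medians of the Per and Dbp clock list were 0.014 without background correction, 0.043 with medians set equal, 0.017 with an offset of 50, 0.014 in the authors' values, 0.032 without a filter, 0.042 over genes detected on all arrays, 0.19 on BeadChip 1, -0.011 with array weights, 0.019 with fry and -0.13 to 0.17 without 1 array. Neutrophil markers had -0.25 with medians set equal, -0.30 over genes detected on all arrays, -0.99 on BeadChip 2 (adjusted p = 0.017) against 1.32 on BeadChip 1 (0.00586), -0.050 with the replicate block, -0.44 without controls 1, 3 and 4 and -0.31 to 0.20 without 1 array. The estimated correlation of the neutrophil list was 0.86, so camera at the preset 0.01 overstated its calls on single BeadChips. ER stress genes had -0.058 with medians set equal, -0.10 on BeadChip 2, 0.040 with array weights, -0.016 without controls 1, 3 and 4, -0.16 with fry and -0.21 to -0.027 without 1 array. Pericentral genes had -0.011, -0.17 and -0.23 with medians set equal, on BeadChip 2 and without controls 1, 3 and 4, and -0.19 to -0.077 without 1 array. Secreted peptides had -0.17 over genes detected on all arrays, -0.14 on BeadChip 1, -0.10 with the replicate block and -0.11 to 0.044 without 1 array. Bile acid genes had -0.088 with medians set equal and -0.27 with fry, p53 targets -0.018 with medians set equal, macrophage markers 0.40 on BeadChip 1 (adjusted p = 0.327) against -0.65 on BeadChip 2 (0.00107), and ribosomal proteins -0.064 on BeadChip 2, 0.0028 without controls 1, 3 and 4 and 0.0089 to 0.080 without 1 array. Median, mean and camera direction differed in sign for bile acid genes (median -0.27, mean 0.01), ER stress genes (-0.16, 0.11), secreted peptides (-0.05, 0.17), neutrophil markers (-0.04, 0.03), p53 targets (0.02, -0.02) and the Per and Dbp clock list (median 0.02, mean 0.03, camera lower).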

Other observations

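None of the values in this part come from tests chosen after the result was seen, apart from the look at Arntl.

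Secreted peptides moved in both directions in knockout liver, with 3 of 21 measured members risen, 2 fallen and 16 not passing (camera adjusted p = 0.858; adjusted over the list alone, 5 rose and 3 fell). Beside Kiss1, which the study's title names, Fst, the activin-binding follistatin, was 4.80-fold higher (limma adjusted p = 5.63e-05) and Inhbe, an activin subunit of hepatocytes, 2.20-fold lower (limma adjusted p = 0.000466). Without background correction their log2 differences were 1.43 and -0.60, against 2.26 and -1.14 with it. In ER stress and the integrated stress response 3 of 17 genes rose, 4 fell and 10 did not pass (camera adjusted p = 0.722; over the list alone, 3 and 5). The transcription factor genes Ddit3 and Atf5 were 3.35-fold and 1.57-fold higher and Asns, the asparagine synthetase, 2.69-fold higher, while Chac1 was 1.75-fold lower. Chac1 did not pass with array medians set equal (limma adjusted p = 0.0646), and the log2 difference of Ddit3 was 1.12 without background correction against 1.74 with it. Of 19 acute-phase genes 1 rose, 4 fell and 14 did not pass (camera adjusted p = 0.261; adjusted over the list alone, 1 and 4), with Saa3 2.40-fold lower, Saa4 1.85-fold lower, Cp 1.54-fold lower and Crp 1.38-fold higher. With array medians set equal neither Cp (limma adjusted p = 0.136) nor Crp (0.0552) passed. Of 70 respiratory chain subunits 2 rose and 68 did not pass (camera adjusted p = 0.144; over the list alone, 2 rose). The pair that rose, Cox7a1 (2.39-fold) and Cox6a2 (1.98-fold), are forms typical of heart and muscle, and Cox6a2 was detected on 2 of 8 control and 6 of 7 knockout arrays. The log2 difference of Cox6a2 was 0.98, but 0.35 without background correction, and it did not pass with array medians set equal (limma adjusted p = 0.271).

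Sex-biased liver genes changed in both directions. Of 10 male-biased genes 4 fell, 1 rose and 5 did not pass, with Cyp4a12a 2.76-fold and Cyp4a12b 2.19-fold lower and Elovl3 3.00-fold higher. The list's camera adjusted p was 0.0907, and 0.0438 without knockout replicate 5; adjusted over the list alone, 5 fell and 1 rose. Of 4 female-biased genes Cyp17a1 (4.46-fold) and Acot3 (2.46-fold) rose, also when adjusted over the list alone (camera adjusted p = 0.164). Of 19 cell cycle genes 4 rose and 15 did not pass (camera adjusted p = 0.164; over the list alone, 7 rose and 3 fell), with Aurka 1.70-fold, Bub1b 1.59-fold, Birc5 1.48-fold and Cdc20 1.41-fold higher. Cdc20 did not pass with array medians set equal (limma adjusted p = 0.0508), nor Birc5 with the mean over its probes (0.0809). None of 10 p53 targets (camera adjusted p = 0.669) or 56 ribosomal protein genes (0.689) passed in limma, with 0 higher and 2 lower, and 2 higher and 1 lower, at an unadjusted p under 0.05.

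Clock genes varied within the groups. None of the 3 measured genes of the Bmal1 phase (camera adjusted p = 0.43) or the 7 of the Per and Dbp phase (0.993) passed in limma, and 0 did at an unadjusted p under 0.05. Arntl, which encodes the clock factor BMAL1, stood at log2 intensities of 6.89 to 7.70 in control replicates 1, 2, 3, 5 and 6 and of 4.98 to 5.12 in control replicates 4, 7 and 8. In the knockouts it ranged from 5.66 to 7.31, and the groups differed by -0.16 (limma adjusted p = 0.874). The times at which livers were taken are not given in the sources used here.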
